A study of Homo sapiens with 12 samples.

How the data were processed

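RNA sequencing libraries from 12 samples of 2 human breast cancer cell lines were described by the labels. Per the labels' protocols, polyadenylated RNA was selected from total RNA with an RNA integrity number of at least 8. The same protocols also describe a mouse mesenchymal line and its adipogenic differentiation, which match none of the samples, and they state different amounts of input RNA. Parts of them may therefore not apply to these libraries. Per the submitters' processing notes, cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3 were named, together with the build GRCh38. The role and order of these tools, the gene annotation and any filter on genes are not given in the sources used here. The authors deposited 2 tables of gene-level counts, one named for each cell line, with Ensembl gene identifiers in the first column.

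The 12 columns of counts were not used. None of their names occurs in the title, description, source name or characteristics of any sample. A column could therefore be tied to control or baicalein only by its position or by its values, and neither was accepted as evidence. Since columns that match no sample were left out altogether, no expression level, sequencing depth, fold change or test of treatment is given. The tests planned before the data were examined, edgeR's quasi-likelihood test within each line and an interaction test between the lines, were not run.

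The identifier column was the part of each table that belongs to no sample, and it was analysed with Python 3.11.15. Identifiers were compared between the tables without version numbers. They were paired with current gene symbols from a gene name table, which named 32069 of the 32098 identifiers found in either table. A gene fixed by an older symbol was also looked up under its GENCODE release 29 symbol. Gene types were taken from GENCODE release 29, which covered 93.5% of the identifiers in both tables, 89.9% of those in the T47D table only and 88.4% of those in the MCF7 table only. RefSeq gene types, matched by symbol, were an alternative. The 31 gene lists and the 15 single genes were fixed before the data were examined. They came from pathways and cell types that fit a flavonoid treatment of luminal breast cancer cells. Further lists among them were about other cell types or RNA quality. The matching alternatives were chosen after seeing the data. Every list member that was not in both tables is named or counted, in place of the rule for named genes, which needs test results.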

Results

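The series addressed how baicalein, a flavonoid of skullcap root, alters gene expression in breast cancer cells. T47D and MCF7, established estrogen receptor-positive lines of the luminal type, were each sampled as control, with no vehicle named in the labels, and after 24 h with 100 uM baicalein, with 3 samples in each of the 4 groups. The growth protocol in the labels names different media for the lines, with insulin for MCF7 alone, but it also describes a mouse line that is not among the samples, so its details are uncertain here. The count columns could not be assigned to control or baicalein from the labels. No comparison of treated with control cells was made, and the effect of baicalein in either line was not analysed here. The gene listing of the table for each line, as used here, is described instead. A listed gene is a row of the table. The rule by which rows were kept is not given in the sources used here, so presence is not read as a level or as an effect of treatment.

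The table named for T47D listed 28848 gene identifiers and the table named for MCF7 listed 28851, with no identifier repeated in either. Both tables shared 25601 identifiers. A further 3247 stood in the T47D table only and 3250 in the MCF7 table only. Protein-coding genes made up 66.6% of the shared identifiers with a GENCODE release 29 type (15949 of 23945). They made up 31.7% (924 of 2919) of those in the T47D table only and 27.5% (791 of 2873) of those in the MCF7 table only. Among identifiers with a RefSeq type, the shares were 78.1%, 46.8% and 41.8%, in the same order. RefSeq types covered only 77.6%, 57.6% and 55.1% of the identifiers in these sets, too few for a check of the shares. These are complete counts of the rows in these tables, and no test was applied. Whether other libraries of the same lines would give the same rows was not tested. The identifiers in the T47D table only or the MCF7 table only are therefore not read as fixed differences between the lines.

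All 15 genes fixed singly were listed in both tables. They included ESR1, the estrogen receptor alpha gene, PGR, the progesterone receptor gene, and GATA3, a luminal transcription factor. The lipoxygenase genes ALOX5, ALOX12 and ALOX15, which encode enzymes of the class that baicalein is known to inhibit, were listed in both. So were CYP1A1, a target of the aryl hydrocarbon receptor, HMOX1, the heme oxygenase gene, TFRC, the transferrin receptor gene, and the cell cycle inhibitor genes CDKN1A and CDKN2A. TP53, CASP3, MYC and MKI67 completed the set.

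Of the 641 distinct genes in the 31 lists, 608 were listed in both tables, 9 in the T47D table only, 13 in the MCF7 table only and 11 in neither table. For 18 lists, every member was in both tables. These included the 37 estrogen receptor targets, the 26 NRF2 targets, the 32 hypoxia targets, the 32 genes of the ATF4 and amino acid response, the 37 genes of DNA replication and S phase, the 30 mitotic genes and the 18 genes of luminal identity. Most protein-coding genes of either table were in both. By GENCODE release 29 types, 15949 were shared, 924 were in the T47D table only and 791 in the MCF7 table only. Complete lists, and the genes fixed singly, are therefore not read as a result about those pathways.

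The list of flavonoid conjugation and export genes had the most members listed in 1 table only, with 8 of its 16 members in both. The UDP-glucuronosyltransferase genes UGT1A1, UGT1A3, UGT1A6, UGT1A9 and UGT1A10, whose enzymes attach glucuronic acid to flavonoids, were in the MCF7 table only. These genes share their 3' exons at a single locus, so reads can be split between them in counting and their separate rows are uncertain. The list had the most such members only with these genes counted separately. GSTP1, a glutathione transferase gene, was in the T47D table only. SULT1E1, an estrogen sulfotransferase gene, and UGT1A8 were in neither table. Of the 9 members of the metallothionein and zinc export list, 4 were in both tables, while MT1A, MT1E, MT1G, MT1H and MT1M were in neither.

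Each remaining incomplete pathway list had 1 or 2 members in 1 table only. Of the 10 aryl hydrocarbon receptor targets, 9 were in both tables. The other was UGT1A6, of the locus with uncertain rows, in the MCF7 table only. SPATA18, a p53 target, PCSK9, a regulator of the LDL receptor, IFI44L, an interferon-induced gene, BCL2A1, an antiapoptotic gene, and ALOX5AP, the gene of the lipoxygenase-activating protein, were in the MCF7 table only. CXCL2, a chemokine gene, PLA2G4A, a cytosolic phospholipase gene, and ZEB2, a mesenchymal transcription factor gene, were in the T47D table only. Among markers of other cell types, 3 of 8 adipocyte genes, 7 of 10 fibroblast genes, 7 of 10 leukocyte genes and 11 of 12 basal epithelial genes were listed in both. ADIPOQ, LPL, PDGFRA, CD3E and CD19 were in the T47D table only, and PPARG, FAP and KRT6A in the MCF7 table only. FABP4, LEP, POSTN and TYROBP were in neither.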

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

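No paired analysis was possible because the count columns carry no name that ties them to a sample, a treatment or a replicate number. Other normalizations, tests and filters, and leaving out each library in turn, were not run, since the comparison of treated with control cells was not made. The alternatives that were run concern the gene listing and were chosen after seeing the data. With current symbols only, 616 list genes were found in the T47D table and 620 in the MCF7 table, against 617 and 621 with GENCODE release 29 symbols added. Among identifiers with a RefSeq type, the protein-coding share was 78.1% in both tables, 46.8% in the T47D table only and 41.8% in the MCF7 table only. Among those with a GENCODE release 29 type, the shares were 66.6%, 31.7% and 27.5%. RefSeq gave a type to 77.6%, 57.6% and 55.1% of all identifiers in these sets, so that alternative is void as a check on the shares. The counts of protein-coding identifiers in the same sets were 15507, 874 and 749 by RefSeq. By GENCODE release 29 they were 15949, 924 and 791, so the counts differed less than the shares.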
